A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

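The series holds 6 two-colour Agilent tiling arrays of fission yeast chromatin immunoprecipitation (ChIP). Per the labels, cells in log phase were grown in rich medium at 30 °C and fixed with 3% paraformaldehyde. For the Pds5 ChIPs, cells were first held at 18 °C for 2 h, and DMA, a protein cross-linker, was added to the fixation. Chromatin was sonicated to fragments of 500 to 1000 bp and precipitated with an antibody against dimethylated H3K9 or against GFP. ChIP DNA and whole-cell extract DNA were amplified by PCR with random primers and labelled with Cy5 and Cy3 respectively, per the labels. The dyes ran the same way on all 6 arrays, so a dye bias shared by the arrays drops out of differences between genotypes but not out of levels.

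Per the file headers, images were quantified with Agilent Feature Extraction 12.0.3.1. The processed signals of each spot are intensity values per the file headers, already background-subtracted and dye-normalised by linear factors, since the recorded lowess factors were 0. Median spot and local background signals are intensity values per the file headers with no correction. The LogRatio column is a log10 ratio of Cy5 over Cy3 per the file headers. Other columns used, per the file headers, are flags for control, outlier, saturated and dim spots. The deposited value table holds log2 ratios. In all 41251 of its positions it lay within 0.01 of the scanner's ratio put on the log2 scale, so its direction (ChIP over extract) and scale were settled and it is not centred. Its column medians were -0.1462 for H3K9me2 in wild type, -0.209 in pds5Δ, -0.087 and -0.0914 for the Pds5-GFP wild-type arrays, -0.072 in swi6Δ and -0.0544 in clr4Δ.

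Each array has 42968 spots, 41551 of them not controls. Control spots were left out, as were spots flagged as outliers: 1306 in wild type and 111 in pds5Δ for H3K9me2, then 72 and 99 in the wild-type Pds5-GFP pair, 82 in swi6Δ and 2 in clr4Δ. The value of a probe is log2 of the processed Cy5 signal over the processed Cy3 signal, minus the array's median, with no loess or quantile step. No spot was saturated, and dim spots were kept.

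The genome build of the array's positions is not given in the sources used here, and tiles of chromosome III run past the end of the reference. Positions printed are therefore the array's own tile positions, with a spacing of 300 bp. Genes and repeats were laid on the tiles by shifting blocks of the reference annotation (assembly ASM294v3) until its base composition followed the extract signal, with shifts on a 50 bp grid. On the left arm of chromosome I, extract signal and base composition correlated at r = 0.461 over probes. For the contig of the silent mating-type region r was 0.394. Of the 41251 chromosome probes, 41119 lay in blocks that could be placed. No coordinate of the reference is printed. Many probes of repeats and chromosome ends carry a suffix in their name that several probes share. Its meaning is not given in the sources used here, and results without them are given as an alternative.

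Regions were the pericentromeric repeats, the central domains of the centromeres, the silent mating-type region, the last 50 kb at each end of chromosomes I and II, and the rDNA probes at the ends of chromosome III. A region's value is the median of its probes. With 1 array per genotype, or 1 mutant array, no region was tested. Its difference was set beside the medians of 10000 random runs of as many neighbouring probes outside heterochromatin, which describes these arrays and is no test between genotypes. The runs were not matched to the region's wild-type ratio. They therefore do not show how an unchanged region at a high ratio would differ. A gene's value is the mean over at least 3 probes inside it. A gene met the H3K9me2 size rule when the arrays differed by 1 or more on the log2 scale and at least 1 of them reached a ratio of 1. It met the Pds5-GFP size rule when the mutant lay 1 or more below, or above, both wild-type arrays. Enriched probes reached a log2 ratio of 1 in a running median of 3 probes.

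Pds5-GFP genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the 4 arrays in 3 groups. The fit has 1 residual degree of freedom, from the wild-type pair, and each lone mutant array is assumed to vary like that pair. A limma contrast between the mutants was run at first and then dropped, since each has 1 array and the spread came from wild type alone. The moderated fit gave a single pooled variance, so the standard error was 0.105 for every gene. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The labels do not say whether the wild-type pair came from separate cultures, so p-values measure the spread between these arrays. On simulated data with the wild-type spread, all 100 genes changed by 1 and all 100 changed by 2 were recovered for swi6Δ and for clr4Δ among 4596 genes, with 6 and 7 unchanged genes called. That simulation gave every gene and array the same noise, the assumption stated above, so recovery of changes of 1 or more was nearly certain. It says nothing of differences under 1, or of genes whose spread is wider than the pooled one. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

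The comparisons, regions, thresholds, gene lists and the rule for naming genes were chosen before the data were examined. Named genes are the 8 largest rises and the 8 largest falls among genes meeting the size rule, members of the lists that met the size rule or the test (up to 8 per list), and pds5, swi6 and clr4. One gene that this rule names is not reported here. The 10 lists were Mmi1-targeted meiotic genes and islands, telomere-linked helicases, heterochromatin factors, cohesin and its regulators, strongly transcribed metabolic genes, heat-shock genes, strain marker genes, ribosomal protein genes, Tf2 retrotransposons and genes within 50 kb of the ends of chromosomes I and II. List medians were set beside 10000 random lists of the same size matched on starting level. tRNA genes were taken at the tiles within 300 bp.

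The alternatives were normexp background correction with an offset of 50, the deposited ratios, loess within arrays, dim probes left out, log ratios scaled to equal deviation, another centring, means in place of medians, chromosome ends of 100 kb, other gene and size rules, a fit that joins both mutants, and leaving out each wild-type array. The files hold no mean spot signals, so normexp ran on median signals, where mean signals had been planned. The alternative with the deposited ratios differs from the main values mainly by keeping the spots flagged as outliers. ChIP signal alone and the omission of probes with a shared suffix were added after seeing the data. An array of a strain without the GFP tag was not analysed here, so the background of the GFP antibody is not known from these arrays.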

Results

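Fission yeast silences its centromeres, mating-type cassettes and chromosome ends in heterochromatin. There the methyltransferase Clr4 places H3K9me2 on histone H3, and the HP1 protein Swi6 binds that mark. Pds5 is a regulator of cohesin, the ring complex that holds sister chromatids together. H3K9me2 was mapped on 1 array of wild-type cells and 1 array of pds5Δ cells. Pds5 fused to GFP was mapped on 2 wild-type arrays, 1 swi6Δ array and 1 clr4Δ array. Ratios are log2 of ChIP over whole-cell extract, centred on the array median. From 98.4% to 99.98% of the spots of an array were well above background in both channels. Over all probes the wild-type Pds5-GFP arrays correlated at r = 0.961 and the H3K9me2 arrays at r = 0.894. Probes are not independent replicates.

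The deleted genes were missing where the labels say so. In the extract channel, the 13 probes of pds5 lay at -6.95 relative to the median of the pds5Δ array, against 0.16 in the H3K9me2 wild type. The 3 probes in the coding part of swi6 lay at -6.85 on the swi6Δ array and the 5 in that of clr4 at -6.55 on the clr4Δ array. On the arrays where the gene is intact, extract values of these probes ran from -1.13 to 0.44.

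The H3K9me2 arrays ask, after the title of the series, what loss of Pds5 does to heterochromatin. The mark was lower in pds5Δ at the pericentromeric repeats and the silent mating-type region. It was higher over part of the right end of chromosome II and over the rDNA at the ends of chromosome III, all of whose probes share a suffix. At the repeats the direction of the difference of medians turns without the probes sharing a suffix. The median change probe by probe of the 56 probes left was -0.28. The repeats (260 probes), which nucleate heterochromatin through RNA interference, had a median of 7.51 in wild type and 6.67 in pds5Δ, a difference of -0.84. The right end of II, a region of 156 probes between tiles 4460700 and 4510500, went from 2.21 to 4.20, a difference of 1.99, which lay in its 102 probes without a shared suffix (1.92 to 4.08) and not in the 54 with one (4.90 to 4.86). The rDNA (72 probes) stood at 3.21 in wild type and 4.46 in pds5Δ, a difference of 1.25. With 1 array per genotype these are differences between 2 arrays, with no replicate check.

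At the single centromeres the repeats differed by -0.84, -0.78 and -0.82 for cen1, cen2 and cen3. None of 10000 random runs of probes outside heterochromatin had a difference as low as that of the repeats. Those runs were not matched on level, and 18 probes outside the regions at the repeats' wild-type ratios had a median change of -0.97. The central domains, which carry the kinetochores, had 3.66 in wild type and 3.43 in pds5Δ. That difference of -0.23 lay at percentile 2.91 of the random runs. These ratios rest on a dim extract, at -3.21 in wild type and -3.60 in pds5Δ relative to the array median. The ChIP signal itself lay near the array median, at 0.04 and -0.38. The silent mating-type region (60 probes), which holds the donor cassettes for mating-type switching, had 6.76 and 6.33, a difference of -0.43 at percentile 0.27. The right end of chromosome I had 5.41 and 5.03, a difference of -0.39 and again below every random run. With loess the central domains differed by less (-0.16), and the other differences grew, to -1.36 at the repeats, -0.78 at the silent mating-type region and -0.84 at the right end of I, and to -2.48, -1.94 and -1.59 with log ratios scaled to equal deviation, where the central domains differed by -1.04 and the right end of II by 1.28. The difference at the right end of II lay above all random runs, which spanned -0.35 to 0.99, and that of the rDNA at percentile 99.9. The left ends of I (5.32 and 5.39) and of II (2.21 and 2.47) differed by 0.07 and 0.26, at percentiles 75.7 and 86.8, and neither direction held. Both turned negative with log ratios scaled to equal deviation (-1.16 and -0.27), and the left end of I also with loess (-0.74), with means over probes (-0.19), on the ChIP signal alone (-0.25) and without the probes that share a suffix (-0.74). Mitochondrial DNA, which has no histones, stood at -2.90 on both arrays.

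**Figure D1:**
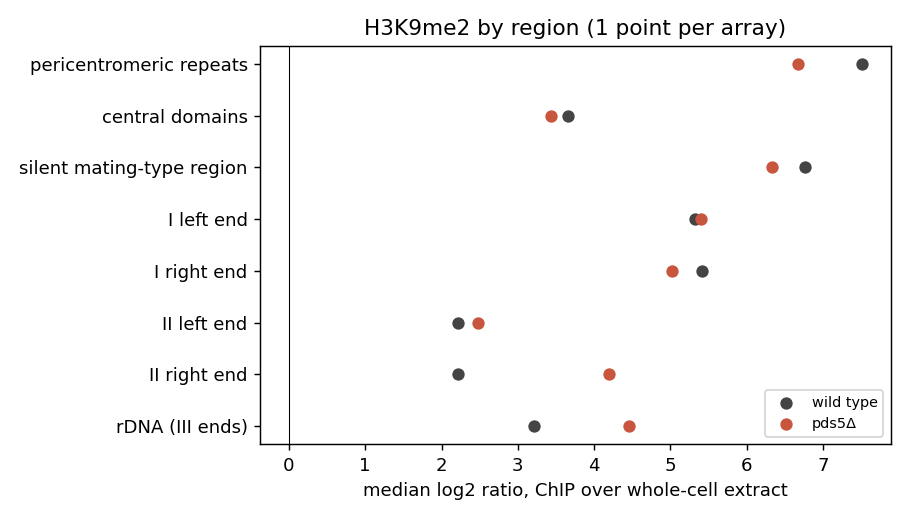
Median log2 ratio of H3K9me2 ChIP over whole-cell extract (x axis) for 8 regions (y axis), with 1 point for the wild-type array and 1 for the pds5Δ array. The right end of II goes from 2.21 to 4.20 and the rDNA from 3.21 to 4.46, while the repeats go from 7.51 to 6.67. The direction of that difference of medians turns when probes with a shared suffix are left out, while the median change probe by probe stays negative. The left end of II turns negative with log ratios scaled to equal deviation, and the left end of I with that, with loess, with means, on the ChIP signal alone and without shared-suffix probes.

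The wider signal at the right end of II came with more enriched probes elsewhere. In wild type 3705 probes and in pds5Δ 5680 probes reached a log2 ratio of 1, with 3455 in common. The pds5Δ array has the wider ratios, and at equal deviation the numbers were 4160 and 5186. Between 50 and 100 kb from the ends of I and II, 405 of 644 probes were enriched in wild type and 602 in pds5Δ. In the last 50 kb of chromosome III, next to the rDNA, the number was 10 of 204 in wild type and 121 in pds5Δ. At a ratio of 3 or more, the right end of II had 40 of its 156 probes in wild type and 156 in pds5Δ.

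**Figure D2:**
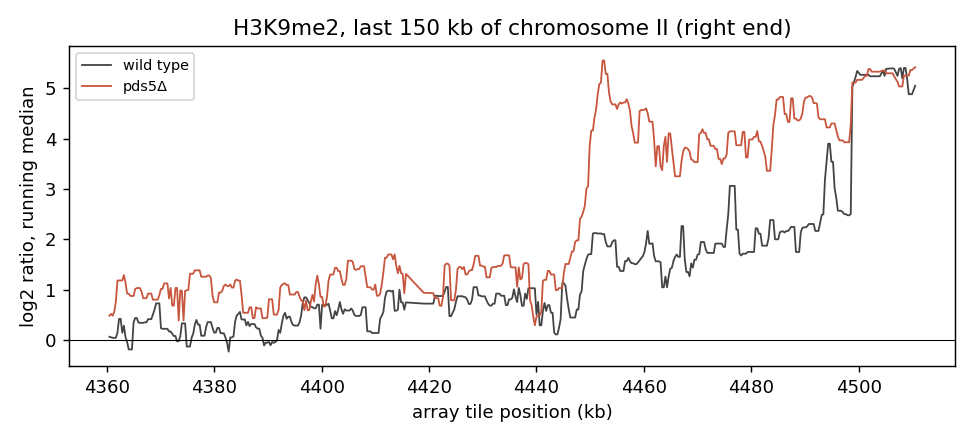
Running median over 5 probes of the log2 ratio of H3K9me2 ChIP over extract (y axis) along the last 150 kb of chromosome II by array tile position in kb (x axis), with 1 line per array. The pds5Δ line stands above the wild-type line over most of the last 50 kb, where the region medians were 4.20 and 2.21.

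By the size rule, 89 of 4570 genes were higher in pds5Δ and 10 were lower. Of the 89, 18 lay within 100 kb of right ends, 8 within 100 kb of left ends and 63 elsewhere. At the right end of II, gal7, gal1 and gal10, which encode enzymes of galactose use, rose from 2.03 to 4.81, from 2.33 to 4.82 and from 2.05 to 4.47. tgd1 overlaps gal10, shares its 11 probes and has the same values. The neighbouring genes fub2 (1.53 to 4.39), nrg1 (1.95 to 4.54), pan5 (2.04 to 4.27), SPBPB2B2.06C (1.87 to 4.09) and say1 (1.38 to 3.61) rose with them. Away from the ends, SPAC1071.09C on chromosome I (tiles 3864600 to 3866700) had the largest rise by this rule, from 0.68 to 4.27. rfc4 and rfc3, which encode subunits of the clamp loader of DNA replication, rose from 0.24 to 3.27 and from -0.14 to 2.66. byr2, a kinase of pheromone signalling, rose from 0.74 to 3.27. The value of pds5 itself (-0.61 and 1.93) met the rule as a ratio of residual signals of the deleted gene, with the ChIP signal at -3.99 against wild type.

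The 10 genes that fell lay in several places. At the right end of I, SPAC186.02C fell from 4.07 to 2.90 and SPAC186.03, all 4 of whose probes carry a shared suffix, from 4.22 to 3.12. Next to centromere 3, ppc1, an enzyme of coenzyme A synthesis, fell from 4.68 to 3.48. ura4, the uracil marker of chromosome III, fell from 6.68 to 5.57, and mae2, a malic enzyme all 6 of whose probes carry a shared suffix, from 6.80 to 5.58. iec1, a subunit of the Ino80 remodeller, fell from 2.06 to 0.79 and rhp7, a repair gene, from 1.26 to 0.08. The meiotic genes ssm4 (4.04 to 2.97) and num1 (2.22 to 1.15), also known as mcp5, fell as well. On the ChIP signal alone SPAC186.02C, SPAC186.03, ppc1, ura4, iec1, rhp7, ssm4 and num1 missed the size rule, and mae2 missed it with 500 bp added on each side, where ura4 turned to 0.20. With the deposited ratios mae2 (-0.76), ura4 (-0.55) and rhp7 (-0.51) missed it as well. Those ratios are the scanner's own and differ from the ones used here mainly by keeping spots flagged as outliers. Such spots numbered 1306 in wild type and 111 in pds5Δ, so these 3 falls depend on which spots are kept.

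Mmi1-targeted meiotic genes and islands had a median difference of -0.44 over 10 measured of 11, at percentile 0.25 of random lists. At equal deviation it was -0.78. Islands are short H3K9me2 patches over genes silenced in growing cells, but not all members carried the mark. In wild type rec8 (0.04), mug10 (0.13), spo5 (0.14), crs1 (0.26) and mug8 (0.64) stood under 1. Their differences, from -0.13 to -0.51, enter the median. Among members above 1, mcp7 and meu1 differed by -0.79 and -0.38. ssm4 and num1 of that list fell, and mei4, the regulator of meiotic transcription, stood at 4.85 in wild type and 4.91 in pds5Δ. Genes within 50 kb of the ends of I and II (31 measured of 48) had a median of -0.08 (-0.49 with loess and -1.24 at equal deviation), with 7 higher and 2 lower. Of the 8 strain marker genes (median 0.30, percentile 98.1), leu1, an enzyme of leucine synthesis, rose from -0.01 to 1.47 (0.91 higher on the ChIP signal alone, under the size rule) and ura4 fell. None of the 16 heterochromatin factors met the size rule (median -0.03). swi6 had 0.00 and 0.25, and clr4 had 0.02 and 0.01. Of the 10 genes of cohesin and its regulators (median -0.10), pds5 alone met it. None met it among 11 measured of 12 strongly transcribed metabolic genes (median 0.26, percentile 98.8), 5 measured of 6 heat-shock genes (0.25), 53 measured of 131 ribosomal protein genes (0.16, percentile 99.9) or 9 measured of 13 Tf2 retrotransposons (0.08). On the ChIP signal alone the medians were -0.01 for metabolic, -0.14 for heat-shock, 0.03 for ribosomal protein and 0.02 for strain marker genes, and Tf2 turned to -0.74 after loess and to -0.03 at equal deviation. Neither of the 2 telomere-linked helicases had enough probes. The 49 tRNA genes in the centromeres, which bound heterochromatin there, had a median of 4.76 in wild type and 4.69 in pds5Δ, and the 117 elsewhere 0.18 and 0.16.

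Without the probes that carry a shared suffix (204 of 260), the difference at the repeats was 0.15 in place of -0.84, with cen1 at -0.33, cen2 at 0.57 and cen3 at 0.45, while the median change probe by probe of the 56 probes left was -0.28. With log ratios scaled to equal deviation 52 genes were higher, 60 were lower and the rDNA differed by 0.39, and on the ChIP signal alone 57 were higher and 1 lower.

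The wild-type Pds5-GFP arrays show where Pds5 lies. Pds5-GFP was highest over heterochromatin: the repeats had 4.04 ± 0.09 (SD, n = 2), the silent mating-type region 3.52 ± 0.05, the right end of I 2.95 ± 0.03 and its left end 2.28 ± 0.06. Without the probes that share a suffix the repeats had 1.88, below the silent mating-type region (3.74) and the left (3.26) and right (3.00) ends of I. The rDNA had 1.13 ± 0.02, the left end of II 0.79 ± 0.02, its right end 0.66 ± 0.03 and the central domains 0.61 ± 0.24. Each of these lay at or above percentile 99.6 of random runs. Along the chromosome arms, probes between convergent genes, where cohesin is known to collect, had a mean of 0.32 ± 0.01, those between divergent genes -0.17 ± 0.03 and those between tandem genes 0.01 ± 0.02. The extract signal of the central domains was dim, at -3.29 relative to the array median, and with normexp background correction their ratio was -0.67.

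The swi6Δ array asks whether Pds5 needs Swi6 at heterochromatin. Pds5-GFP was far lower there in swi6Δ, at 0.28 or less in every region but the repeats and the rDNA. The silent mating-type region had 0.28, a difference of -3.24 from wild type. The right end of I had 0.12 (-2.83) and its left end 0.11 (-2.17). The repeats kept 1.58, a difference of -2.46. Probe by probe, the median change there was -2.41 for the 204 with a shared suffix and -0.75 for the 56 without. The wild-type arrays differed from each other by 0.12 or less in these regions.

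In swi6Δ the left and right ends of II had 0.14 and 0.13, differences of -0.65 and -0.53, below every random run. The rDNA had 0.92, a difference of -0.21 at percentile 0.69. The central domains had 0.02, a difference of -0.59, where the wild-type arrays were 0.34 apart. By the size rule 22 genes fell and 0 rose, 16 of them within 100 kb of right ends and 4 of left ends. With limma 143 of 4596 genes were lower and 33 higher (388 and 246 at an unadjusted p under 0.05). Of the 143, 36 lay within 100 kb of right ends, 24 of left ends and 14 within 20 kb of a centromere. The largest fall was at pdc102, a pyruvate decarboxylase gene at the right end of I (tiles 5548500 to 5550000), with 2.92 ± 0.09 in wild type and a difference of -3.23 (SE 0.105). Near it SPAC750.08C (-3.21), SPAC186.07C (-3.10), SPAC186.08C (-3.10), SPAC186.06 (-2.96), gdt1 (-2.83), SPAC186.04C (-2.76) and SPAC750.01 (-2.69) fell. Outside the ends mae2 (-2.88) and ura4 (-2.61) were the 2 that met the rule. All probes of SPAC750.08C and of mae2 carry a shared suffix, so where their signal arises is not settled. The surroundings of ura4 did not share its level, as the last paragraph describes.

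**Figure D3:**
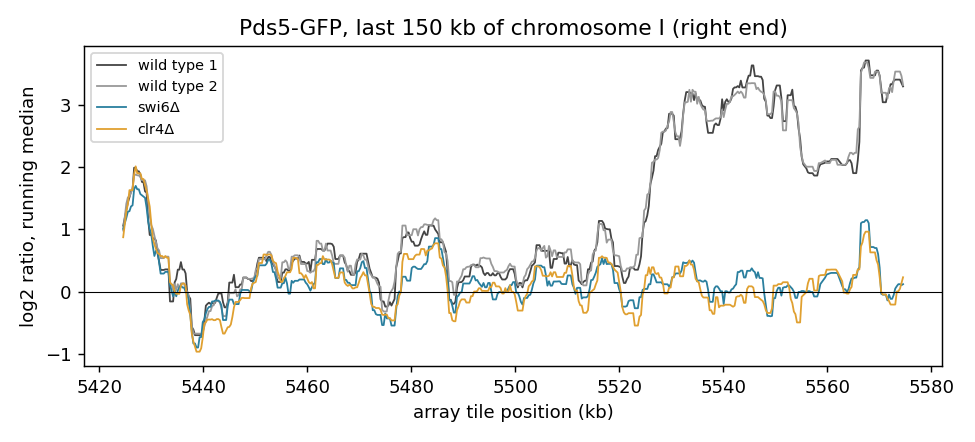
Running median over 5 probes of the log2 ratio of Pds5-GFP ChIP over extract (y axis) along the last 150 kb of chromosome I by array tile position in kb (x axis), with 1 line per array. Over the last 50 kb the wild-type lines stand high, with a region median of 2.95, and the swi6Δ and clr4Δ lines lie near 0, with medians of 0.12 and 0.06.

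All 32 measured of 48 genes within 50 kb of the ends of I and II were lower in swi6Δ when adjusted over the list alone, and 28 over all genes (median -1.61). Of 10 Mmi1-targeted genes (median -0.14, percentile 0.68), mei4 fell (-0.34, adjusted p = 0.034 by limma), and 4 fell when adjusted over the list alone. Among 16 heterochromatin factors (median 0.01), rdp1, the RNA-dependent RNA polymerase of RNA interference, had a limma difference of 0.44 (adjusted p = 0.0019), but its wild-type arrays were as far apart as 0.88 and 1.28, against 1.52 in swi6Δ, and with normexp the difference was -0.10. The -0.44 of swi6, deleted here, is in part a ratio of residual signals, with ChIP and extract at -4.79 and -4.36 against wild type. Adjusted over the list alone, 1 rose and 1 fell. pds5 and clr4 had -0.05 and 0.11 and passed no threshold. None of 10 genes of cohesin and its regulators (-0.03), 11 strongly transcribed metabolic genes (-0.03), 5 heat-shock genes (-0.02) or 9 Tf2 retrotransposons (0.09) passed the test, over all genes or adjusted over the list alone. Of 8 strain marker genes (-0.20, percentile 0.15), ura4 fell, and 2 fell when adjusted over the list alone. Of 54 ribosomal protein genes (-0.01), rps1701 fell (-0.42), in the list alone as well. On the ChIP signal alone the metabolic median was 0.31 and that of Tf2 -0.06. No telomere-linked helicase was measured. tRNA genes in the centromeres had medians of 2.19 and 2.14 in the wild-type pair and 1.02 in swi6Δ, and those elsewhere 0.24, 0.30 and 0.09. Between convergent and divergent genes the difference of means was 0.49 ± 0.02 in wild type and 0.50 in swi6Δ, but 0.55 and 0.24 with normexp.

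Against the wild-type array of the same slide alone, the swi6Δ differences were -2.52 at the repeats, -3.21 at the silent mating-type region and -2.80 at the right end of I. The limma counts moved with the processing, to 311 higher and 1226 lower with normexp, 73 and 155 with log ratios scaled to equal deviation, 15 and 38 on the ChIP signal alone and 2 and 61 with loess, which ended the calls of mei4 (-0.32), rdp1 (0.33), swi6 (-0.27) and rps1701 (-0.35). The central domains differed by 1.27 with normexp, the rDNA by 0.78 on the ChIP signal alone, and without the probes that carry a shared suffix the repeats differed by -0.53, with cen1 at 0.07 and 8 genes meeting the size rule.

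The clr4Δ array asks the same of Clr4, whose loss removes H3K9me2 itself. Pds5-GFP was lower at the same regions. The silent mating-type region had 0.33, a difference of -3.19, and the right end of I 0.06 (-2.88). The repeats had 1.07, a difference of -2.97, and the left end of I 0.09 (-2.19). Probe by probe, the median change at the repeats was -3.18 with a shared suffix and -0.55 without. The central domains had 0.54, a difference of -0.06 at percentile 5.97. With either wild-type array left out it ran from -0.24 to 0.11, and it was -0.34 with means over probes and 0.18 with normexp.

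In clr4Δ the left and right ends of II had 0.11 and 0.11, differences of -0.68 and -0.55, and the rDNA 0.58, a difference of -0.55. The size rule again gave 22 genes that fell and 0 that rose, and all 22 were shared with swi6Δ. With limma 109 genes were lower and 73 higher (265 and 380 at an unadjusted p under 0.05). Of the 109, 32 lay within 100 kb of right ends, 20 of left ends and 16 within 20 kb of a centromere. SPAC186.08C (-3.39), SPAC186.07C (-3.29), SPAC750.08C (-3.17), pdc102 (-3.14), gdt1 (-3.00), SPAC186.06 (-2.98), SPAC186.04C (-2.83) and mae2 (-2.78) had the largest falls, and ura4 fell by 2.78. SPAC750.01 followed with -2.60. The limits given for SPAC750.08C, mae2 and ura4 in swi6Δ hold here as well.

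**Figure D4:**
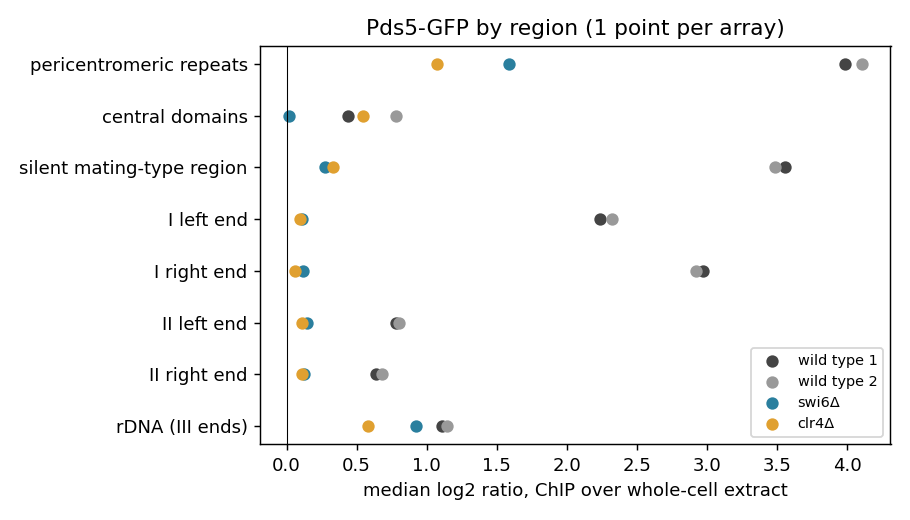
Median log2 ratio of Pds5-GFP ChIP over whole-cell extract (x axis) for 8 regions (y axis), with 1 point for each of the 4 arrays. At the silent mating-type region the wild-type mean is 3.52 and the swi6Δ and clr4Δ points are 0.28 and 0.33, while the order at the central domains and the direction at the rDNA turn with normexp and with the ChIP signal alone respectively.

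All 32 genes within 50 kb of the ends were lower in clr4Δ when adjusted over the list alone, and 31 over all genes (median -1.53). Of 10 Mmi1-targeted genes (median -0.08, percentile 1.76, and -0.21 on the ChIP signal alone), meu1 was called lower by limma (-0.37), in the list alone as well. It lies within 20 kb of a centromere. Its wild-type H3K9me2 of 2.71 is near the median of 2.76 in the first 25 kb beside the centromere of I. A change of that flank and a change of a meiotic island cannot be told apart there. Among 16 heterochromatin factors (0.06), rdp1 had a limma difference of 0.37, smaller than the gap between its wild-type arrays (0.88 and 1.28, against 1.45 in clr4Δ). chp2, a chromodomain protein, differed by 0.33 (adjusted p = 0.042 by limma), from -0.29 and -0.11 in the wild-type pair to 0.13. Both also passed adjusted over the list alone. pds5 and swi6 had 0.02 and -0.03 and passed no threshold. The 0.10 of clr4, deleted here, is in part a ratio of residual signals, with ChIP and extract at -2.29 and -2.39 against wild type. None of 10 genes of cohesin and its regulators (0.01) or 9 Tf2 retrotransposons (0.11) passed the test, over all genes or adjusted over the list alone, and the Tf2 median was -0.54 on the ChIP signal alone and 0.36 with loess. Of 11 strongly transcribed metabolic genes (0.14, percentile 99.8, but 0.05 with loess and 0.08 on the ChIP signal alone), tef101, a translation elongation factor, passed in both counts with 0.33, from 0.25 and 0.48 in the wild-type pair to 0.70. Of 5 heat-shock genes (-0.06), 0 passed over all genes and 1 was lower adjusted over the list alone. Of 8 strain marker genes (-0.15, percentile 0.22), ura4 fell in both counts, and of 54 ribosomal protein genes (0.09, percentile 99.8), rps1701 fell (-0.35) in both. tRNA genes in the centromeres had a median of 0.96 and those elsewhere 0.32. Between convergent and divergent genes the difference was 0.63.

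Of the limma calls, 69 genes were lower in both mutants, where independent lists of these sizes would share 3.39, and 7 were higher in both, against 0.524. Both comparisons use the same wild-type arrays, so part of the excess may come from them. Across genes the differences of the mutants correlated at r = 0.715, against 0.333 in 100 simulations with no effect, and their covariance was 0.0352 against 0.0037. The clr4Δ array is alone on its slide, so slide and genotype cannot be told apart for it. In clr4Δ the limma counts were 19 higher and 53 lower with loess, 4 and 32 with normexp and 19 and 44 on the ChIP signal alone, and each of these ended the calls of meu1, rdp1, chp2, tef101 and rps1701. Their differences often stayed as large while the median standard error went from 0.105 to 0.109, 0.145 and 0.187: chp2 had 0.31, 0.29 and 0.36, meu1 -0.31, -0.33 and -0.42, and tef101 0.28, 0.52 and 0.31, while rdp1 had 0.36, 0.42 and 0.17 and rps1701 -0.31, -0.30 and -0.17. On the ChIP signal alone the rDNA differed by 0.46, and without the probes that carry a shared suffix the repeats differed by -0.77 and 8 genes met the size rule.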

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

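All tests of explanations in this part were chosen after the results they bear on were seen.

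H3K9me2 at the pericentromeric repeats was lower in pds5Δ by the median of all probes. More repeat DNA in the pds5Δ extract is argued against, since the ChIP signal alone differed by -0.78. A compression of high ratios over the whole array may account for it: 18 probes outside heterochromatin at the same wild-type ratios had a median change of -0.97, and all 18 went down. Of these, 17 carry Pds5-GFP at a ratio of 1 or more and 1 does not, and that 1 changed by -2.16, too few to tell compression from a loss of the mark. The 18 were also picked by their own wild-type value, which by itself pulls their change down, and 7 of them carry a shared suffix. A difference between the strains of the 2 arrays, apart from pds5, is untested as well.

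H3K9me2 over the right end of II and the rDNA was higher in pds5Δ. An array-wide rise of intermediate ratios stays open. Probes outside heterochromatin at the wild-type ratios of these regions changed by -0.069 (451 probes) and -0.29 (53 probes), but they cannot decide it. They were picked by their own wild-type value, which by itself pulls their change down. Their pool also holds marked flanks: 25 to 50 kb from the centromeres, 96.6% of probes reached 1 or more in wild type. Both rises were smaller but still positive with loess and at equal deviation. Less of this DNA in the extract is argued against as the whole cause, since the ChIP signal alone differed by 1.93 and 0.96, although the extract of the rDNA was lower by a difference of -0.36. A biological effect of losing Pds5 on these regions is a hypothesis that could account for the rise. That hypothesis stays open beside an array-wide rise and any other difference between the 2 cultures, which 1 array per genotype cannot exclude.

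Pds5-GFP was lower at heterochromatin in swi6Δ and clr4Δ. At the repeats, probes with a shared suffix carried most of the fall, with median changes of -2.41 and -3.18. Those without one changed by -0.75 and -0.55. More repeat DNA in the extract is argued against, since the ChIP signal alone differed by -2.04 and -2.62, and so is a difference between slides for swi6Δ, which differed by -2.52 from the wild-type array of its own slide. A general loss of strong ratios was tested in 3 versions: at the repeats' own ratios 20 probes outside heterochromatin changed by -2.43 and -2.80, but all 17 of them with a wild-type H3K9me2 value carry that mark, so at this level the question stays open. At ratios of 2 to 3, a band and a split by H3K9me2 chosen after that result, such probes changed by -0.067 and 0.036, those without H3K9me2 by 0.022 and 0.12, and those with it by -1.04 and -1.06, which argues against a general loss there. A dependence of Pds5 on Swi6 and Clr4 where H3K9me2 lies may therefore stand as a hypothesis for that range, with slide and genotype confounded for clr4Δ.

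The extract channel, which no comparison uses by itself, drew attention because it was higher in a mutant than in both wild-type Pds5-GFP arrays at several stretches of repeated DNA. Relative to the wild-type mean, the repeats together had 0.32 in swi6Δ and 0.57 in clr4Δ, but those of cen2 had 0.07 and -0.09, beside 0.32 and 0.47 at cen1 and 0.55 and 0.67 at cen3. The silent mating-type region had 0.31 and 0.27. The left end of I had 0.35 and 0.25, its right end 0.31 and 0.29, and the rDNA 0.91 and 0.43. Probes of the pNSU clones, which hold sequence from chromosome ends, had 1.05 in swi6Δ and 0.77 in clr4Δ, where the wild-type pair itself lay at 0.96 and 1.58.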

How the results depend on the processing

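The 149 results were recomputed 1306 times with 1 choice changed, except that normexp also started from uncorrected median signals in place of processed ones. Of these values 946 were the same, 286 moved, 54 kept their direction but passed the threshold no longer, 2 passed it newly and 18 reversed. For genes, the same meant an unchanged direction and threshold. For Pds5-GFP regions and intergenic classes it meant a shift within the spread of the wild-type pair. Leaving out 1 wild-type array shifts the wild-type mean by less than that spread by construction. Region and intergenic values of that setting could therefore not count as moved, and their label says nothing of robustness. H3K9me2 regions have no replicates, so their shifts were set against the spread of random runs along the same arrays. Counts were the same when they stayed within a fixed fold of the count in the report. A reversal here is a change of sign of a value that was called in the report, and the sign differed for 50 values in all. Leaving out dim probes, eBayes with a trend and medians for intergenic classes moved none. The ChIP signal alone and the omission of probes with a shared suffix were chosen after seeing the data. Calls of named genes that ended numbered 16 on the ChIP signal alone, 11 with 500 bp added, 10 with loess, 8 with the deposited ratios, 6 with normexp and 3 with equal deviation. All reversed values, and the moved values of whole regions and counts, follow by setting, with differences from wild type and, in brackets, genes shared with the result in the report. Another 115 moved values, of single centromeres and other parts, are not listed: 46 were larger in size than in the report, 62 smaller and 7 of the other sign. Of these, 25 came with loess (8 larger, 15 smaller), 25 with means (7 and 18), 16 with equal deviation (9 and 6), 16 with normexp (11 and 2), 14 on the ChIP signal alone (3 and 10), 11 without shared suffixes (0 and 11), 5 with the other centring and 3 with the deposited ratios (all larger). Where no reason is given, the cause was not tested.

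On the ChIP signal alone, H3K9me2 in pds5Δ differed by -0.25 at I left, -0.60 at I right and 0.96 at the rDNA. swi6Δ differed by -2.04 at the repeats, -2.89 at the mating-type region, -1.60 at I left, -2.28 at I right, -0.70 at II left, -0.50 at II right, 0.78 at the rDNA and 0.79 at III left rDNA. clr4Δ differed by -2.62 at the repeats, -3.07 at the mating-type region, -1.76 at I left, -2.45 at I right, -0.74 at II left, 0.46 at the rDNA and 0.31 at III left rDNA. The size rule gave 57 higher (49 shared) and 1 lower (1 shared) in pds5Δ and 1 higher (0 shared) in clr4Δ. limma called 15 higher (3 shared) and 38 lower (36 shared) in swi6Δ and 19 higher (4 shared) and 44 lower (30 shared) in clr4Δ. pds5 had -3.99 in pds5Δ. At an adjusted p under 0.1, limma called 55 higher (33 shared) in swi6Δ and 123 higher (73 shared) in clr4Δ. With both mutants joined, limma gave 1 comparison of the joined group with wild type, with 6 genes higher (all 6 called in swi6Δ and in clr4Δ) and 81 lower (75 called in swi6Δ, 73 in clr4Δ). Centred outside heterochromatin, Pds5-GFP in wild type was 0.82 at II left, 0.69 at II right and 1.16 at the rDNA.

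With 500 bp added on each side of a gene, the size rule gave 5 lower (3 shared) in pds5Δ, 38 lower (22 shared) in swi6Δ and 38 lower (22 shared) in clr4Δ. limma called 38 higher (31 shared) in clr4Δ. ura4 had 0.20 in pds5Δ. With genes of at least 1 probe, the size rule gave 35 lower (22 shared) in swi6Δ and 35 lower (22 shared) in clr4Δ. With ends of 100 kb, H3K9me2 in pds5Δ differed by 0.57 at I left and -0.16 at I right. Pds5-GFP in wild type was 0.78 at I left, 1.13 at I right, 0.62 at II left and 0.45 at II right. swi6Δ differed by -0.70 at I left, -1.01 at I right, -0.53 at II left and -0.37 at II right. clr4Δ differed by -0.65 at I left, -1.06 at I right, -0.46 at II left and -0.40 at II right. With loess within arrays, H3K9me2 in pds5Δ differed by -1.36 at the repeats, -0.78 at the mating-type region, -0.74 at I left, -0.84 at I right, 1.54 at II right and 0.66 at the rDNA. Pds5-GFP in wild type was 3.27 at the repeats, 3.11 at the mating-type region, 1.80 at I left, 2.64 at I right and 0.99 at the rDNA. swi6Δ differed by -2.09 at the repeats, -2.86 at the mating-type region, -1.88 at I left, -2.53 at I right and -0.41 at the rDNA. clr4Δ differed by -2.62 at the repeats, -2.92 at the mating-type region, -1.90 at I left, -2.63 at I right, -0.73 at II left, -0.62 at II right and -0.68 at the rDNA. limma called 2 higher (2 shared) and 61 lower (61 shared) in swi6Δ and 19 higher (19 shared) and 53 lower (53 shared) in clr4Δ. Convergent minus divergent was 0.44 in wild type, 0.45 in swi6Δ and 0.58 in clr4Δ.

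With log ratios scaled to equal deviation, H3K9me2 in pds5Δ differed by -2.48 at the repeats, -1.04 at central domains, -1.94 at the mating-type region, -1.16 at I left, -1.59 at I right, -0.27 at II left, 1.28 at II right and 0.39 at the rDNA. swi6Δ differed by -0.16 at the rDNA. clr4Δ differed by -0.57 at the rDNA. The size rule gave 52 higher (52 shared) and 60 lower (10 shared) in pds5Δ. limma called 73 higher (33 shared) in swi6Δ and 46 higher (43 shared) in clr4Δ. With means over probes, H3K9me2 in pds5Δ differed by -0.19 at I left, -0.61 at I right and 1.58 at II right. Pds5-GFP in wild type was 3.48 at the repeats, 0.85 at central domains, 3.25 at the mating-type region, 2.21 at I left, 2.77 at I right, 1.06 at II left, 0.87 at II right and 1.36 at the rDNA. swi6Δ differed by -1.95 at the repeats, -2.79 at the mating-type region, -2.005 at I left, -2.61 at I right, -0.93 at II left, -0.75 at II right and -0.17 at the rDNA. clr4Δ differed by -2.48 at the repeats, -0.34 at central domains, -2.94 at the mating-type region, -2.08 at I left, -2.68 at I right, -0.98 at II left, -0.78 at II right and -0.41 at the rDNA. With normexp, Pds5-GFP in wild type was -0.67 at central domains, 3.75 at the mating-type region, 3.20 at I right, 0.86 at II left, 0.82 at II right and 1.17 at the rDNA. swi6Δ differed by -2.76 at the repeats, 1.27 at central domains, -3.57 at the mating-type region, -2.53 at I left, -3.16 at I right, -0.88 at II left, -0.91 at II right, -0.66 at the rDNA, 1.29 at cen1 central domain, 1.36 at cen2 central domain and 0.49 at cen3 central domain. clr4Δ differed by -3.37 at the mating-type region, -3.14 at I right, -0.81 at II left, -0.77 at II right and -0.61 at the rDNA. The size rule gave 7 higher (0 shared) in swi6Δ. limma called 311 higher (1 shared) and 1226 lower (117 shared) in swi6Δ and 4 higher (4 shared) and 32 lower (32 shared) in clr4Δ. Convergent minus divergent was 0.55 in wild type, 0.24 in swi6Δ and 0.70 in clr4Δ. rdp1 had -0.10 in swi6Δ. Without probes that carry a shared suffix, H3K9me2 in pds5Δ differed by 0.15 at the repeats, -0.74 at I left, -0.74 at I right, 0.57 at cen2 repeats, 0.45 at cen3 repeats and 0.42 at cen1 central domain. Pds5-GFP in wild type was 1.88 at the repeats, 3.74 at the mating-type region, 3.26 at I left, 3.00 at I right, 0.68 at II left and 0.59 at II right. swi6Δ differed by -0.53 at the repeats, -3.44 at the mating-type region, -2.81 at I left, -2.89 at I right, -0.43 at II left, -0.46 at II right and 0.068 at cen1 repeats. clr4Δ differed by -0.77 at the repeats, -3.38 at the mating-type region, -3.02 at I left, -3.02 at I right, -0.54 at II left and -0.49 at II right. The size rule gave 8 lower (8 shared) in swi6Δ and 8 lower (8 shared) in clr4Δ.

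With the deposited ratios, which keep the spots flagged as outliers, limma called 20 higher (18 shared) in swi6Δ and 42 higher (35 shared) in clr4Δ. At a size rule of 1.5-fold, genes numbered 204 higher (89 shared) and 37 lower (10 shared) in pds5Δ. At a threshold of 1.5, 3697 probes were enriched in pds5Δ.

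With normexp the median difference of all genes in swi6Δ was -0.23, against 0.01 with the processing of the report. Its 311 and 1226 genes therefore include a shift of genes in general. Each array was centred on the median of its probes, so this is not a shift of the whole array, and its cause was not tested. Genes of at least 1 probe add genes, and a lower threshold or size rule adds calls by construction.

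With either wild-type array left out, swi6Δ differed by -2.52 to -2.40 at the repeats and by 0.16 to -1.59 at mitochondrial DNA, where the wild-type pair had -0.96 and -2.71. clr4Δ differed by -3.03 to -2.91 at the repeats and by -0.24 to 0.11 at the central domains. The size rule gave 22 to 24 lower genes in swi6Δ and 23 in clr4Δ. The limma test without a wild-type array was not run, since no residual degree of freedom remains, and slide as a block was not run for the same reason. No paired analysis was possible because only the wild-type Pds5-GFP arrays carry numbers. Signal over background limits the central domains, whose extract lay at -3.29.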

Other observations

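The distances, stretches and genes below were chosen after the H3K9me2 and Pds5-GFP profiles were seen, and no test was planned for them.

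H3K9me2 in pds5Δ was higher than in wild type in the flanks of the centromeres beyond 25 kb, and beyond 50 kb from the ends of I and II. The values of this paragraph were not recomputed at equal deviation. The pds5Δ array has the wider ratios, which by itself raises positive ones. Small rises may therefore not hold, such as those 25 to 50 kb from the centromeres and 50 to 100 kb from the right end of I (0.12). Between 50 and 100 kb from the edge of the centromeres, the median ratio was 0.84 in wild type and 1.49 in pds5Δ, and the share of probes at a ratio of 1 or more went from 31.8% to 87.1%. The median change per probe there was 0.57 for chromosome I, 0.68 for II and 0.62 for III. Nearer the centromeres it was -0.29 within 25 kb and 0.24 between 25 and 50 kb, and beyond 300 kb, up to 500 kb, it was -0.03. Between 100 and 150 kb from the chromosome ends the median change was 0.57 at the left and 0.73 at the right end of I, and 0.53 and 0.69 at the ends of II. At the right end of III the last 25 kb went from 0.32 to 2.02 and the next 25 kb from -0.20 to 1.49, with a median change of 0.12 between 50 and 100 kb. At its left end the change was 0.51 between 25 and 50 kb, 0.05 between 50 and 100 kb and -0.19 between 100 and 150 kb.

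Stretches of at least 10 changed probes, each higher or lower by 1 or more, numbered 32 higher and 0 lower in pds5Δ. The stretches were not recomputed at equal deviation, a setting in which genes lower by the size rule outnumbered those higher. The balance of higher and lower stretches may therefore not hold. Of the 32, 18 lay within 200 kb of a chromosome end, 10 within 200 kb of a centromere, 1 on a pNSU clone and 3 elsewhere, the deleted pds5 gene among them. The longest ran on II from tile 4446000 to 4493700, with 158 of its 159 probes changed, and went from 1.79 to 4.13. It spans pho84 and pho1, a phosphate transporter and an acid phosphatase, as well as the gal genes. On III a stretch from tile 2412900 to 2428500, which holds ade5 of purine synthesis, went from -0.15 to 1.79. On I a stretch from tile 3834900 to 3840900 near the centromere, which holds the pyruvate kinase gene pyk1, went from 1.52 to 3.24. On the ChIP signal alone these stretches changed by 2.11, 1.96 and 1.66.

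The pds5Δ array had wider ratios than the wild-type one, with a median absolute deviation of 0.450 against 0.358. Outside heterochromatin, 1417 of 38404 probes reached 1 or more in wild type and 3074 in pds5Δ, while 190 and 643 lay at -1 or less. Single probes at a ratio of 1 therefore include noise, and 260 changed downward by 1 or more beside 779 upward.

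ura4 stood out from its surroundings on chromosome III. Its 4 probes had a median H3K9me2 ratio of 6.70 in wild type and 5.75 in pds5Δ, while 16 probes from 1.5 to 6 kb before it had 0.01 and -0.08, and 16 after it -0.21 and -0.32. Its Pds5-GFP ratios were 3.37 and 3.102 in the wild-type pair, 0.61 in swi6Δ and 0.43 in clr4Δ. ura4 is widely inserted as a reporter into heterochromatin, and the labels do not state whether these strains carry such a copy.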
